A study of Rattus norvegicus with 16 samples.

How the data were processed

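Each of the 16 arrays was a 1-colour Agilent rat miRNA array read for 1 pool of RNA from 3 rats, with 4 pools in each of 4 groups: control and CI-AKI plasma, and control and CI-AKI kidney. Per the labels' protocols, total RNA was isolated and labelled with Agilent's miRNA labelling kit. Per the file headers, the intensity of each spot was extracted with Agilent Feature Extraction 10.7.3.1. The deposited files give a background-corrected processed signal per spot, a median signal and background, a total signal per miRNA and a detection call per miRNA. Each array held 7000 spots for 350 miRNAs, with 938 probes, 1 to 4 per miRNA. Per the file headers and positions, the 8 plasma arrays lay on slide 1 and the 8 kidney arrays on slide 2, with 1 scan each, and on both slides odd columns held control and even columns CI-AKI pools. The labels name biotin as the label, while the protocol names a kit used with a 1-colour dye; the values do not depend on which name is right.

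The authors also deposited a table of log2 values. Set against the scanner values, its columns had correlations of 0.9884 to 0.9982 with the same array, and its quantiles differed by at most 0.016 between arrays, so it holds log2 values that were quantile-normalized over all arrays, controls included; each column's median was 2.28, and the exact steps are not given in the sources used here. It served as an alternative. The total signal of an undetected miRNA in the scanner files was its error estimate, with 0 exceptions, so it was used only as an alternative.

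The processed signals were averaged over the spots of a probe, without outlier-flagged and control spots, then over the probes of a miRNA. Each array was divided by its 75th percentile over the miRNAs detected on all arrays of its tissue (74 in plasma, 163 in kidney, and 65 over all 16 arrays for the comparison of tissues) and multiplied by the geometric mean of these percentiles. Values below a floor were set to the floor, and log2 was taken, which understates the change of dim miRNAs. The floor was the median over arrays of the lowest detected signal (0.976 in plasma and 1.79 in kidney). On plasma control pool 4 and CI-AKI pool 4 the lowest detected scaled signals were 20.9 and 18.4, far above the plasma floor. Undetected miRNAs kept values above the floor there, such as miR-466b at 16.0 and miR-494 at 19.7 in control pool 4. A bound was given where a miRNA was detected on no array of a group: the bright group's mean against the dim group's mean of, per array, the higher of its own signal and the lowest detected signal. No miRNA was saturated. The probes of a miRNA moved apart by more than 0.5 on the log2 scale in opposite directions for 1 of 95 miRNAs in plasma and 0 of 174 in kidney. MiRNA names are those of the array design. Genomic positions are not given, since no genome was used here.

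MiRNAs detected on all 4 arrays of at least 1 compared group were tested: 96 in plasma, 176 in kidney, 87 for the interaction and 178 between tissues. Tests were limma's lmFit and eBayes (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 21 miRNA lists were tested with camera at a correlation of 0.01 where at least 3 members were tested, with an estimated correlation and fry beside it; fry tests whether members move, on balance, one way. Single values per array were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 from Python 3.11.15 with pandas 2.3.3. The groups, tests, lists, the rule for named miRNAs and the alternatives were fixed before the data were examined, except where a choice is described as made afterwards. Named are all miRNAs past the threshold up to 10 each way, the 10 smallest p where under 5 passed, up to 4 members of each list, all members of the miR-30 and followed-up lists, the 5 with the highest signal in each tissue, the 10 smallest p of the interaction, the 5 largest differences each way between tissues, and miR-21, miR-122 and miR-210. The differences between tissues were ranked only among miRNAs detected on all control arrays of both, a restriction made afterwards because the others were not measured on every array. Named outside that rule, after their values were seen, are miR-347, the miRNAs at a bound or detected on some arrays between tissues, and miR-200a there.

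The number of pools limits the precision. Over the 96 tested plasma miRNAs the median SD within groups was 0.513 on the log2 scale with all pools, 0.408 without pool 4 of both groups, and 0.513, 0.483 and 0.519 without pool 1, 2 or 3, a comparison added after the data were seen and not tested. On simulated data with 20 changed miRNAs in each of 20 simulations, a log2 change of 1 was recovered in 43.5% of cases among 96 plasma miRNAs, 97% among 176 kidney miRNAs, 59% among 87 for the interaction and 65% among 178 between tissues. A change of 2 was recovered in 91.5%, 98.5%, 88.5% and 84% of cases, with 0.35, 0.9, 0.8 and 0.75 false calls per simulation. The simulated values of a miRNA had the same spread on every array, without weak arrays, a floor or a detection filter. A list shifted by 1, the let-7 family, was called in 20 of 20 simulations in plasma and in kidney. The simulated miRNAs varied independently, whereas the let-7 members had estimated correlations of 0.458 in plasma and 0.654 in kidney. The shift of 1 was also far larger than the median let-7 difference of -0.06 in kidney. These counts therefore do not show how the list test behaves on members that vary together or on small shifts.

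Groups were taken from the sample titles. Letter codes in the sample descriptions disagree with them between tissues: of 8 letters, 6 have opposite treatments in plasma and kidney. The comparisons keep the titles' groups, and each tissue was also fitted with the treatment that the other tissue gives to its letters, an alternative added after the data were seen. Pools share numbers across groups in the labels. In plasma, pools with the same number deviated together from their group means (correlations 0.224, 0.488, 0.619 and 0.603 for pools 1 to 4). The numbers may thus pair the plasma samples, although the labels give no rats or days shared between treatments. Pools with different numbers had correlations of -0.6 to 0.389, the highest for control pool 2 with CI-AKI pool 3. The group means include pool 4, whose arrays were weak in both groups and can move the other pools alike. The correlations were not computed without pool 4. The fit with the pool number as a block is therefore given beside the plasma result where it changes the call.

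The alternatives were the percentile over all miRNAs, quantile normalization, median scaling, no scaling, the authors' total signal per miRNA, the brightest probe, the authors' log2 table, looser and stricter detection filters, floors at 0.5 times and 2 times the value, the pool number or the slide row as a block, eBayes with trend and robust estimation, all groups in 1 fit, and leaving out each pool in turn. Normexp background correction with an offset of 50 had been fixed for the mean spot signal. The files used here hold the median spot signal, so normexp was run on that instead. An offset of that size shrinks the log2 differences of dim miRNAs. Scaling to the labelling spike-in, leaving out both pool 4 plasma arrays and pairing the plasma and kidney pools of a treatment by number for the interaction were added after the data were seen.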

Results

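MicroRNAs (miRNAs), short RNAs that lower the output of target mRNAs, were measured in blood plasma and kidney of rats given an iodinated contrast medium and of control rats given saline. All 24 male Sprague-Dawley rats had been kept without water for 3 days and had received furosemide, a diuretic, at 10 mg/kg; 12 rats then received Omnipaque (iohexol, 350 mg iodine per ml) and 12 received saline, both at 10 ml/kg, and samples were taken 8 h later. The treated rats are referred to here by the model's name, contrast-induced acute kidney injury (CI-AKI). RNA of 3 rats was combined into each pool, which gave 4 pools per group and tissue and 16 arrays, each reading 350 rat miRNAs with 20 spots per miRNA. Within a tissue the pools are separate sets of rats, so the spread between pools is a spread between means of 3 animals. With 24 rats in all, the plasma and kidney pools of a treatment came from the same rats. The labels do not settle which plasma pool shares rats with which kidney pool. Groups were taken from the sample titles, with which the treatment labels go together. The samples also carry letter codes, 8 letters used once in each tissue. The labels give 6 of the 8 letters opposite treatments in plasma and kidney and 2 the same. What the letters stand for is not stated. If each marks 1 set of rats, each of these 6 letters has a wrong treatment label in 1 of the tissues, and the comparisons of treatment given here would not hold there.

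Array signals of different miRNAs have no common scale, since their probes bind and are labelled differently. Signal served only to choose which miRNAs to name. The plasma miRNAs so chosen were miR-451, a red blood cell miRNA, at a scaled signal of 3554 ± 1460 (SD, n = 8 arrays), miR-21 at 2262 ± 664, miR-23a at 1794 ± 255, the myeloid miR-223 at 1745 ± 579 and the liver miRNA miR-122 at 1593 ± 753. In kidney they were miR-21 at 5899 ± 714, let-7f at 5211 ± 316, let-7a at 4118 ± 248, miR-22 at 4004 ± 361 and miR-30c at 3324 ± 283. All 16 arrays detected 65 miRNAs, all plasma arrays 74 and all kidney arrays 163, and 88 miRNAs were detected on none.

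Arrays of the fourth plasma pool stood apart in both groups. The control pool 4 had 84 detected miRNAs and a total miRNA signal of 3484, and the CI-AKI pool 4 had 95 and 7068. The other plasma control pools had 188, 200 and 208 detected miRNAs with totals of 58685, 89125 and 123239, and the other CI-AKI plasma pools 156, 211 and 189 with totals of 24171, 109432 and 67318. The synthetic RNA added before labelling read 51.8 and 164.1 on the pool 4 arrays against 928 to 3155 on the other plasma arrays. Kidney control pools had 179, 195, 169 and 178 detected miRNAs and totals of 89065, 119803, 112063 and 91501. Kidney CI-AKI pools had 216, 216, 174 and 189 with totals of 124853, 116820, 59735 and 117950.

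**Figure D1:**
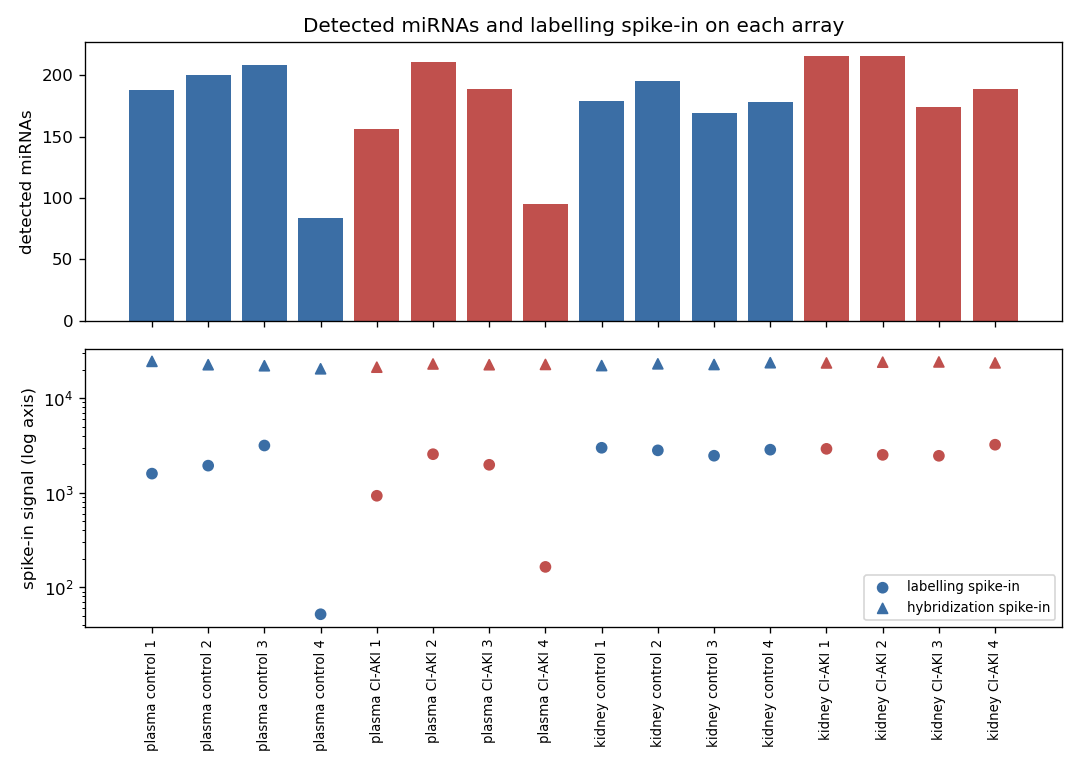
Upper panel, number of detected miRNAs (bars, from 0) on each of the 16 arrays; lower panel, signal of the labelling spike-in (circles) and the hybridization spike-in (triangles) on a log axis, control pools in blue and CI-AKI pools in red. The pool 4 plasma arrays have 84 and 95 detected miRNAs and labelling spike-in signals of 51.8 and 164.1, while their hybridization spike-in signals are 20432 and 22719.

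The number of miRNAs detected and the array signal before scaling were compared first, since scaling would remove a change shared by most miRNAs. In plasma, 170 ± 57.9 miRNAs were detected in control pools and 163 ± 50.5 in CI-AKI pools (SD, n = 4), a difference of -7.25 (exact permutation test, two-sided, p = 0.886). In kidney the numbers were 180 ± 10.8 and 199 ± 20.8, a difference of 18.5 (exact permutation test, p = 0.229). The log2 signal before scaling differed by -0.14 in plasma and by -0.04 in kidney (exact permutation p = 0.914 for each). The smallest p these 70 labellings can give is 0.0286. The sign of 3 of these differences rested on single pools. For detected miRNAs in plasma it was 2.75, 5.42 and 15.3 without control pool 2, control pool 3 or CI-AKI pool 4. For signal in plasma it was 0.11, 0.23, 0.38 and 0.66 without control pools 1, 2 or 3 or CI-AKI pool 4, and in kidney 0.041 and 0.20 without control pool 2 or CI-AKI pool 3.

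The kidney comparison asked which miRNAs differed in the organ 8 h after contrast medium. In kidney, miR-327 rose from a scaled signal of 2.06 ± 0.914 in control pools to 26.1 ± 5.58 in CI-AKI pools (SD, n = 4), miR-466b rose from 3.17 ± 0.427 to 6.38 ± 0.390, and miR-494, a member of the imprinted Dlk1-Dio3 miRNA cluster that has been linked to acute kidney injury, rose from 16.2 ± 1.57 to 28.4 ± 7.20. Each was higher in 4 of 4 CI-AKI pools than in any control pool. No miRNA fell. Among miRNAs named for their signal, miR-21 had a log2 difference of -0.0014 (SE 0.12), let-7f of -0.083 (SE 0.07) and miR-30c of 0.13 (SE 0.09), and none of these passed the test.

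In limma with Benjamini-Hochberg adjustment, 3 of 176 tested kidney miRNAs passed adjusted p 0.05, all higher, and 11 had an unadjusted p under 0.05, all higher. For miR-327 the log2 difference was 3.52 (SE 0.21, adjusted p = 5.8e-06). It was detected on 0 of 4 control arrays, where it has only a bound, and the CI-AKI level was at least 10.6-fold higher. For miR-466b the log2 difference was 1.02 (SE 0.10, adjusted p = 0.000287), with detection on 1 control array and 4 CI-AKI arrays. For miR-494 it was 0.78 (SE 0.16, adjusted p = 0.0475). The groups did not overlap for 9 miRNAs, where chance gives 2.86% of those tested, or 5. The rows of the slide each held 2 pools of each group; the log2 differences within the upper and lower row were 3.13 and 3.92 for miR-327, 1.07 and 0.96 for miR-466b, and 0.98 and 0.58 for miR-494. Both miR-327 probes were higher, by 2.95 and 3.82 on the log2 scale, and both miR-494 probes, by 0.79 and 0.75. The miR-466b probes differed: 1 was higher by 1.06, with no overlap between the groups. The other was higher by 0.33 with overlapping groups, at mean signals of 1.36 in control and 2.41 in CI-AKI pools. The rise of miR-466b thus rests mainly on 1 probe.

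**Figure D2:**
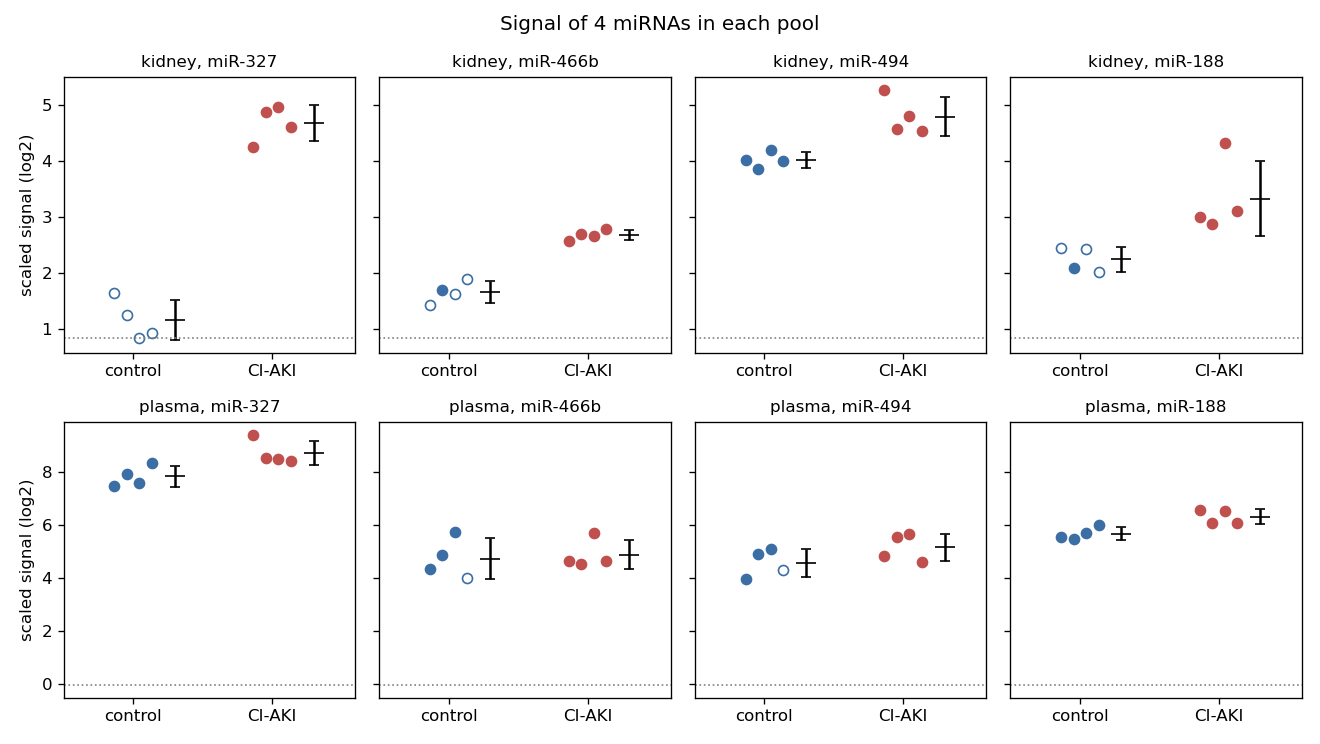
Scaled signal (log2) of miR-327, miR-466b, miR-494 and miR-188 in each pool (points, open where the miRNA was not detected) with mean and SD (bars, n = 4), control in blue and CI-AKI in red, kidney in the upper and plasma in the lower panels; the dotted line is the floor. Every CI-AKI kidney pool lies above every control pool for the 4 miRNAs, of which 3 passed the test in kidney and none in plasma.

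Among the kidney miRNAs with the smallest p that did not pass, the log2 differences were 0.44 (SE 0.11, adjusted p = 0.115) for miR-31, 1.08 (SE 0.29, adjusted p = 0.169) for miR-188, 0.25 (SE 0.07, adjusted p = 0.194) for miR-27a and 0.25 (SE 0.08, adjusted p = 0.253) for miR-24-2*. MiR-31 passed with the percentile over all miRNAs (adjusted p = 0.0466) and with median scaling (0.0498), within a range of 0.0466 to 1 over all alternatives. The differences were 0.19 for miR-24, 0.15 for miR-27b and 0.28 for miR-7a*. The difference for miR-188 was 0.68 in the upper and 1.49 in the lower slide row, and it was detected on 1 control array and 4 CI-AKI arrays. MiR-188 passed without CI-AKI pool 3 (log2 difference 0.74, adjusted p = 0.0196), with the total signal per miRNA (2.44, adjusted p = 0.00355), in the authors' processed values (1.52, adjusted p = 0.0372) and with scaling to the labelling spike-in (adjusted p = 0.00411), within a range of 0.00355 to 1 over all alternatives.

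The call for miR-494 was lost in 18 of 25 alternatives. Among these were quantile normalization (adjusted p = 0.234), no scaling (0.716), median scaling (0.0601), the total signal per miRNA (0.0611), the brightest probe (0.12), the authors' processed values (0.192), detection on at least 1 array (0.0929) or on every array (0.093), all 4 groups in 1 fit (0.64) and scaling to the labelling spike-in (0.157). Its adjusted p was 0.16, 0.121, 0.0995 and 0.158 without control pools 1 to 4 and 0.0552 and 0.112 without CI-AKI pools 2 and 3, and 0.086 with the slide row as a block, within a range of 0.0165 to 1 over all alternatives. The calls of miR-327 and miR-466b held without each pool; with normexp background correction none of the 3 passed (miR-327 log2 difference 0.46), and miR-466b was lost with quantile normalization (adjusted p = 0.2), without scaling (0.0878) and with all 4 groups in 1 fit (0.401), within a range of 2.85e-05 to 1. Treatment and slide column could not be told apart, since odd columns held control and even columns CI-AKI pools. With the treatment that the plasma labels give to the letter codes, a regrouping made afterwards, 0 of 172 kidney miRNAs passed in limma and 7 had an unadjusted p under 0.05. MiR-327 was not among the 172, since the detection filter left it out of that regrouping, so its call was not retested there.

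Of the 21 miRNA lists, 18 had at least 3 members tested in kidney, and 1 passed in camera (limma). All 8 let-7 family members were lower (median log2 difference -0.06, camera adjusted p = 0.0223), with 0 members passing over all miRNAs and 0 adjusted over the list alone. With an estimated correlation the let-7 adjusted p was 0.805, and fry gave an adjusted p of 0.527; 0 lists passed in either. The let-7 call was also lost without control pool 4 (adjusted p = 0.137), CI-AKI pool 1 (0.255) or CI-AKI pool 3 (0.126), with quantile normalization (0.574), without scaling (0.969), in the authors' processed values (0.504) and scaled to the labelling spike-in (0.97), within a range of 9.41e-05 to 0.97 over all settings. With the percentile over all miRNAs and without CI-AKI pool 3, 7 of 8 members were lower, and 6 of 8 without CI-AKI pool 1.

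The kidney injury list had 11 tested members, 7 with a higher and 4 with a lower mean; miR-494 passed, and 2 members, miR-494 and miR-188, passed adjusted over the list alone, while miR-34a stood at -0.15, miR-146a at -0.033 and miR-223 at 0.013 (camera adjusted p = 0.674). The Dlk1-Dio3 cluster had 3 tested members, all with a higher mean (median 0.35, adjusted p = 0.281); 1 of them, miR-494, passed over all miRNAs and adjusted over the list alone. The median was that of miR-409-3p (SE 0.28), whose difference was 0.015 without CI-AKI pool 3 and 0.0087 and 0.69 in the upper and lower slide row. Without that pool the list's median was 0.24 over 4 tested members, and 2 of 3 members were higher with quantile normalization and without control pool 3; with detection on at least 1 array the list passed (13 members, adjusted p = 0.000725, within a range of 0.000725 to 0.644). In the hypoxia list, 5 of 6 means were higher (median 0.11, adjusted p = 0.31, and 0.016 with normexp, within a range of 0.016 to 0.97), with miR-210, the classic hypoxia-induced miRNA, at 0.20 (SE 0.13) and 1 member, miR-27a, passing adjusted over the list alone. The miRNAs followed up by the study, miR-188, miR-30a and miR-30e, had differences of 1.08, 0.076 and 0.028, and 1 of 3 passed adjusted over the list alone (adjusted p = 0.31 for the list). That list was chosen on these samples, so its count is not independent evidence. The same holds for miR-188 as a member of the kidney injury list.

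Lists that describe the make-up of the kidney gave no call and had 0 members passing, over all miRNAs or adjusted over the list alone. The miR-30 family, abundant in kidney epithelium, had 5 of 5 means higher (median 0.076, adjusted p = 0.415), with miR-30b-5p at 0.19 and miR-30d at 0.050; the sign of the list's members was not the same under every scaling, with 4 of 5 higher after quantile normalization, without scaling and in the authors' processed values. Of the tubule-enriched miRNAs, 2 of 3 were higher (median 0.011, adjusted p = 0.641), with miR-204 at 0.043 and miR-192 at -0.05. The epithelial miR-200 family had 4 of 5 higher (median 0.059, adjusted p = 0.641), with miR-200c at 0.15 and miR-200a at -0.0024. The endothelial list had 2 of 4 higher (adjusted p = 0.641), with miR-126 at -0.0063 and miR-221 at -0.096, and the stromal and smooth muscle list 3 of 5 (adjusted p = 0.674), with miR-145 at 0.10 and miR-143 at -0.035.

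Markers of blood cells in the kidney pools did not pass either. The erythroid list had 2 of 4 means higher (adjusted p = 0.863), with miR-451 at 0.26 (SE 0.18) and miR-16 at -0.013. The platelet list had 2 of 3 higher (adjusted p = 0.641) and the leukocyte list 2 of 5 (adjusted p = 0.517), with miR-142-3p at -0.13 and miR-150 at 0.059. The neural list had 3 of 3 higher (median 0.15, adjusted p = 0.606), with miR-9 at 0.20. The p53 targets had 1 of 4 higher (adjusted p = 0.31), the miR-17-92 cluster and paralogs 2 of 9 (adjusted p = 0.31) with miR-19a at -0.24, the miR-29 family 2 of 3 (adjusted p = 0.761) with miR-29a at 0.069, and the miR-15/16 family 1 of 5 (adjusted p = 0.571). The muscle list had 1 tested member, miR-499, at -0.064, the liver list 2, and the miR-290 cluster 0, too few for a list test. Camera compares a list with the other miRNAs, and its direction was down although median and mean were above 0 for the tubule-enriched, endothelial, stromal and miR-29 lists. The median of 12 of the 18 kidney lists turned sign in at least 1 of 24 alternatives: in 10 for the endothelial, 9 for the tubule-enriched, 9 for the miR-29, 7 for the platelet, 5 for the kidney injury and 4 for the stromal list, and in 1 each for the miR-200, erythroid, leukocyte, miR-15/16, miR-17-92 and neural lists.

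The plasma comparison asked whether circulating miRNAs differed after contrast medium. No plasma miRNA passed the test. The largest differences by p were in miR-327, whose signal was 237 ± 67.9 in control and 444 ± 162 in CI-AKI pools (SD, n = 4), in miR-199a-3p, with a log2 difference of -0.72 (SE 0.26), and in miR-188, at 51.9 ± 8.99 and 81.4 ± 15.5. The liver miRNA miR-122 had a difference of -0.61 (SE 0.57), with no settled direction: it was 0.26 without both pool 4 arrays, 0.005 without CI-AKI pool 4, and 0.35 and -1.58 in the upper and lower slide row. That of miR-21 was -0.0064 (SE 0.32).

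In limma, 0 of 96 tested plasma miRNAs passed adjusted p 0.05 (smallest adjusted p = 0.836), and 5 had an unadjusted p under 0.05, of which 3 were higher and 2 lower in CI-AKI pools. The log2 difference was 0.89 (SE 0.31) for miR-327 and 0.64 (SE 0.25) for miR-188, each detected on all plasma arrays. It was 0.75 for miR-874, -0.9995 for miR-215, -0.89 for miR-335, -0.64 for miR-195, 0.54 for miR-291a-5p, 0.60 for miR-494 and -0.52 for miR-26b; with normexp it turned to 0.38 for miR-335 and 0.31 for miR-195. Within the upper and lower slide row the differences were 1.29 and 0.49 for miR-327, 0.83 and 0.46 for miR-188, and 0.75 and 0.45 for miR-494. MiR-494 was not detected in control pool 4, where its scaled signal of 19.7 stood above the floor. The groups did not overlap for 5 miRNAs, where chance gives 2.7. The median SE of a log2 difference was 0.349 in plasma and 0.092 in kidney, and simulated plasma changes of 1 and 2 on the log2 scale were recovered in 43.5% and 91.5% of cases. Those simulations had no weak arrays, floor or detection filter, so the rates may not hold for the real plasma arrays. With the treatment that the kidney labels give to the letter codes, also chosen afterwards, 0 of 96 plasma miRNAs passed in limma and 6 had an unadjusted p under 0.05. The difference for miR-327 was then -0.85 (SE 0.33), a change of sign that largely follows from turning 6 of 8 treatments.

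The plasma result was run again without the pool 4 arrays of both groups, a choice made after the arrays were seen. With 3 pools per group, 0 of 182 miRNAs passed in limma (smallest adjusted p = 0.0616) and 32 had an unadjusted p under 0.05. With the pool number as a block as well, 1 passed, miR-347, with a log2 difference of 1.56 (SE 0.28, adjusted p = 0.0411); without the block its adjusted p was 0.0616. The median log2 difference of all tested plasma miRNAs was -0.086. It moved to 0.26 without the pool 4 arrays, to -0.23 without scaling and with the percentile over all miRNAs, and to 0.13 with median scaling. With scaling to the labelling spike-in it was -0.47, and with normexp 0.38. The plasma differences given here did not have that median subtracted and are to be read beside it.

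None of the 14 lists with at least 3 members tested in plasma passed in camera, with an estimated correlation or in fry, and 0 members of any list passed, over all miRNAs or adjusted over the list alone. The miRNAs followed up by the study had the smallest list p (median 0.34, camera p = 0.0087, adjusted p = 0.122, and 0.719 with an estimated correlation), with miR-188 at 0.64, miR-30a at 0.34 and miR-30e at 0.32. This list was chosen on these samples and is not independent evidence; scaled to the labelling spike-in, 2 of its 3 members were below 0. It passed with quantile normalization (adjusted p = 0.028), in the authors' processed values (0.0359) and with detection on every array (0.0326), within a range of 0.028 to 0.301. In the miR-30 family 3 of 5 means were higher (median 0.32, adjusted p = 0.526), with miR-30d at 0.48 and miR-30b-5p at -0.21, while 5 of 5 were higher without both pool 4 arrays (median 0.58), with median scaling, with normexp and in the authors' processed values, 4 of 5 with quantile normalization, and 1 of 5 scaled to the spike-in. In the let-7 family 6 of 7 were lower (median -0.40, adjusted p = 0.239), with miR-98 at -0.66 and let-7i at 0.085; with normexp 3 of 7 were lower, without both pool 4 arrays 5 of 8 (median -0.075), and without CI-AKI pool 3 the median was -0.092. Without CI-AKI pool 4 the list passed (adjusted p = 0.0262, within a range of 0.0262 to 0.844).

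The stromal and smooth muscle miRNAs had 3 of 3 lower (median -0.38, adjusted p = 0.226), with miR-143 at -0.38, and the miR-15/16 family 4 of 4 lower (median -0.35, adjusted p = 0.282). Among blood cell markers, the erythroid list had 1 of 4 higher (adjusted p = 0.952, and 0.0457 with normexp, within a range of 0.0457 to 0.997), with miR-451 at -0.088 and miR-144 at 0.43, the platelet list 0 of 3 (adjusted p = 0.526), and the leukocyte list 2 of 5 (adjusted p = 0.952), with miR-223 at -0.30 and miR-142-5p at 0.10. The kidney injury list had 2 of 7 higher (camera adjusted p = 0.907), with miR-494 at 0.60 and miR-192 at -0.50. Its other higher member, miR-188, is also on the list of miRNAs followed up by the study. The endothelial list had 0 of 3 higher (adjusted p = 0.526) with miR-126* at -0.43, the hypoxia list 1 of 4 (adjusted p = 0.907) with miR-27a at 0.090, the miR-17-92 cluster and paralogs 2 of 8 (adjusted p = 0.952) with miR-25 at 0.17, the miR-29 family 2 of 3 (adjusted p = 0.952) with miR-29b at -0.27, and the Dlk1-Dio3 cluster 2 of 3 (adjusted p = 0.526) with miR-300-5p at -0.22. Camera's direction was up although median and mean were below 0 for the kidney injury, erythroid and miR-17-92 lists; for the miR-29 list the median was above 0, at 0.049, while the mean was -0.05 and camera's direction down. The median of 13 of the 14 plasma lists, all but the miR-15/16 family, turned sign in at least 1 alternative. Without both pool 4 arrays it was above 0 for the stromal (0.12, 4 of 5 higher), hypoxia (0.13, 5 of 6), kidney injury (0.12, 7 of 11), leukocyte (0.081, 3 of 5), endothelial (0.063, 3 of 4), miR-17-92 (0.036, 7 of 10) and platelet (0.035, 2 of 3) lists. The tubule, muscle, liver and p53 lists had 2 tested members each, the neural list and the miR-290 cluster 1, and the miR-200 family 0.

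Whether contrast medium had a different effect in plasma and kidney was tested as an interaction. Of the miRNAs tested in both tissues, miR-327 differed: its rise in kidney of 3.52 stood beside a plasma difference of 0.89, an interaction of -2.63 (SE 0.37). Since miR-327 was detected on 0 of 4 kidney control arrays, this value depends on the floor: it was -2.87 at 0.5 times and -1.95 at 2 times the floor (limma adjusted p = 0.00171 and 0.00296). The tissues share rats, which the fit did not use. With plasma and kidney pools of the same treatment and number taken as pairs, a choice made afterwards, the SE was 0.44 (adjusted p = 0.00863). The difference for miR-466b was 1.02 in kidney and 0.14 in plasma (interaction -0.87, SE 0.45), for miR-335 0.50 and -0.89 (interaction -1.39, SE 0.50), and for miR-199a-3p -0.068 and -0.72 (interaction -0.65, SE 0.26), none of which passed.

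In limma 1 of 87 miRNAs passed, miR-327 (adjusted p = 0.000302), and 6 had an unadjusted p under 0.05. Among those not passing, the interaction was -0.42 for miR-23a, -0.42 for miR-24, -0.67 for miR-195, -0.34 for miR-23b, -0.50 for miR-26b and -0.52 for miR-126*. Without plasma CI-AKI pool 2, 4 miRNAs passed: miR-195, miR-199a-3p, miR-327 and miR-335; without scaling or with normexp 0 passed. Across the 87 miRNAs the log2 differences of plasma and kidney had a Pearson correlation of 0.446 and a Spearman correlation of 0.379, and 54 had the same sign in both; miRNAs are not independent replicates. With the treatment of each letter code taken from the other tissue, the correlation was -0.394 for regrouped plasma and -0.542 for regrouped kidney arrays. That regrouping turns 6 of 8 treatments, so the change of sign largely follows from the 0.446 and does not tell which labels are right.

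**Figure D3:**
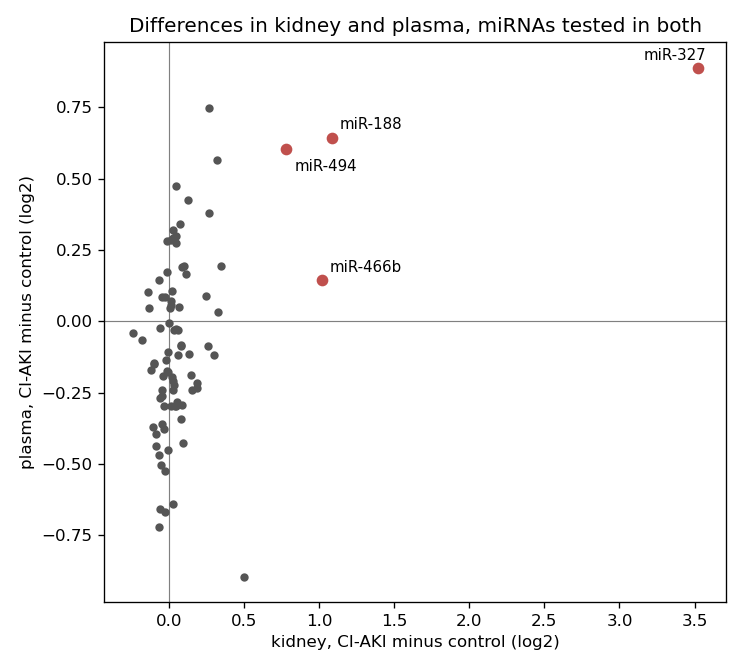
Log2 difference, CI-AKI minus control, in kidney (horizontal axis) and plasma (vertical axis) for the 87 miRNAs tested in both tissues, 1 point per miRNA. The named points are miR-327, miR-466b and miR-494, which passed in kidney, and miR-188, which passed in neither; miR-327 lies at 3.52 in kidney, a value that depends on the floor, and 0.89 in plasma.

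Control pools of both tissues were compared to describe what each material holds. Among the 66 miRNAs detected on all control arrays of both tissues, miR-223 was 48.8-fold, miR-451 44.9-fold and the lymphocyte miRNA miR-150 43.9-fold higher in plasma, let-7d* 23.3-fold and miR-142-5p 22.6-fold. Of the same 66, the largest kidney differences were in let-7f (8.74-fold), let-7a (4.32-fold), miR-30c (3.91-fold), miR-10b (3.43-fold) and let-7d (3.28-fold). Others were detected on only some control arrays of 1 tissue and are given without a rank. Among them, miR-133b (91.6-fold, detected on 3 kidney arrays), miR-335 (49.0-fold, 1 array) and miR-188 (46.1-fold, 1 array) were higher in plasma. In kidney, miR-200b (49.2-fold, detected on 3 plasma arrays), miR-194 (48.1-fold, 2 arrays) and let-7e (16.5-fold, 3 arrays) were higher. The values of miR-200b and miR-194 moved with the floor, to 58.5-fold and 57.2-fold at 0.5 times and to 41.4-fold and 40.4-fold at 2 times the floor. At 2 times the floor miR-133b stood at 88.8-fold, miR-335 at 46.4-fold and miR-188 at 38.3-fold, and let-7e stayed at 16.5-fold. The 7 miRNAs detected on all plasma control arrays and on no kidney control array were miR-122, miR-215, miR-327, miR-1, miR-300-5p, miR-423 and miR-296*, with plasma levels at least 3478-fold, 672-fold, 402-fold, 128-fold, 87.8-fold, 38.8-fold and 11.7-fold higher. MiR-196b was at least 18.2-fold higher in kidney. Each named difference is a comparison of 4 pools with 4, taken as independent although both tissues came from the same rats. Which miRNAs were detected on all, some or no plasma control arrays depends in part on the weak control pool 4, with 84 detected miRNAs.

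In limma 138 of 178 miRNAs passed, 59 higher in kidney and 79 higher in plasma. The number passing was 176 without the weak plasma control pool 4 and 184 without both pool 4 plasma arrays. Of these, 133 and 131 were among the 138. With all control pools, 14 were detected on all kidney and no plasma control arrays and 7 the reverse. Of the blood cell lists, 4 of 4 erythroid and 5 of 5 leukocyte members were higher in plasma, and of the platelet miRNAs 2 of 3 were higher in plasma and 1 in kidney. Of the miR-17-92 cluster and paralogs, 9 of 9 were higher in plasma. The let-7 family had 7 of 8 higher in kidney and the miR-200 family 4 of 5, such as miR-200a (log2 difference 4.47, SE 0.17, detected on 3 plasma arrays), while 1 of the miR-200 members did not pass. The miR-30 family had 2 higher in kidney, 1 in plasma and 2 not passing. Higher in kidney against plasma were 2 and 7 members of the kidney injury list, 2 and 1 of the tubule list, 2 and 1 of the liver list, 2 and 1 of the neural list, 1 and 2 of the muscle list, 1 and 4 of the stromal list, 1 and 3 of the endothelial list, 2 and 3 of the hypoxia list, 2 and 1 of the p53 targets, 2 and 0 of the miR-29 family, 0 and 4 of the miR-15/16 family, 0 and 2 of the Dlk1-Dio3 cluster, and 1 and 1 of the miRNAs followed up by the study; the other tested members did not pass, and no member of the miR-290 cluster was tested. The median of a list turned sign without scaling for the kidney injury (0.67), platelet (0.74), stromal (0.67), endothelial (1.37), hypoxia (1.37) and miR-15/16 (0.45) lists, and with normexp for the tubule (-0.22), neural (-1.28) and p53 (-0.84) lists; the endothelial median was also above 0 with quantile normalization (0.19) and in the authors' processed values (0.21), and the hypoxia median with each other scaling (0.036 to 1.37). Without scaling 0 of 9 miR-17-92 members, 1 of 4 erythroid and 2 of 5 leukocyte members passed. Since each tissue lay on a slide of its own, tissue and slide cannot be told apart. The median log2 difference was -0.40, and the split of 59 higher against 79 lower in kidney was 80 against 55 with quantile normalization, 45 against 12 without scaling and 83 against 53 in the authors' processed values. It was 16 against 57 with normexp.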

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

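The counts of other splits of the pools, the correlation between tissues over relabelled plasma arrays and the correlation without the called miRNAs were fixed before their results; the tests of plasma carry-over, background, slide column, the weak plasma arrays, relabelling within plasma pairs and regrouping by letter code were chosen only after the results they bear on were seen.

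The rises of miR-327, miR-466b and miR-494 in kidney, a count of 3, were set against other groupings of the pools in the main setting. Of the 35 splits of the 8 kidney arrays, 1, the real one, had 3 passing miRNAs, against at most 1 in any other. MiR-327 was detected on the 4 CI-AKI kidney arrays alone, and the detection filter was applied anew in each split. It could thus be tested in no other split, and miR-466b, detected on 1 control array and 4 CI-AKI arrays, in few others. The other splits could therefore hardly reach the real count, so they do not decide on chance. The share of 1 of 35 is also the smallest they can give. Of the 8 splits that part all 4 same-number pairs, 1 reached the count, too few to decide. With quantile normalization, without scaling or with all 4 groups in 1 fit the count was 1, and the splits were not run there. Plasma left in the tissue may be weighed because miR-327 was at least 402-fold higher in plasma than in kidney control pools, but a share large enough for the smallest need, 1.25% for miR-327, would have brought miR-122 to 38.0, whereas its mean signal in the CI-AKI kidney pools was -0.132 (SD 0.125, n = 4), which argues against plasma as the whole source of the rises. Of 2 plasma-only miRNAs with a higher plasma signal than miR-327, 0 were detected in CI-AKI kidney. Among those with a lower plasma signal, miR-296* and miR-423 were each detected on 1 CI-AKI kidney array, and miR-1 and miR-300-5p on 0. These counts decide nothing on plasma as part of the rises, since they are few and signals of different miRNAs have no common scale. Higher background is also argued against, since the negative controls differed by 0.28 while the smallest rise in signal was 3.21. The array column on the slide cannot be told apart from treatment, because 0 columns held both, and an effect of contrast medium stays open beside it, as does a wrong treatment label, since 6 of 8 letter codes have opposite treatments in the 2 tissues.

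The weak arrays of pool 4 in plasma point to the labelling step. The labelling spike-in was lower by 41.8-fold in the control and 13.1-fold in the CI-AKI pool 4 against the other pools, beside drops of the miRNA signal of 23.6-fold and 9.19-fold, which is consistent with a loss at labelling. The hybridization spike-in was at most 1.153-fold lower, which argues against weak hybridization or scanning. Less miRNA in these pools is argued against as the whole cause, since dividing by the labelling spike-in left drops of 0.565-fold and 0.703-fold, that is, no drop. No biological explanation was tested.

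The log2 differences of plasma and kidney were correlated across miRNAs. The correlation of 0.446 over 87 miRNAs was reached by 1 of 70 labellings, the real one (highest other 0.394). The one-sided permutation p was 0.0143, the smallest they can give. These labellings ignore that the pool numbers may pair the plasma samples. Of the 16 labellings that keep the pairs, 1 reached it (p = 0.0625, the smallest these permutations can give), so unrelated plasma effects stay open. Without the 3 called kidney miRNAs the correlation was 0.324 over 84 miRNAs, above the bound fixed for them alone, but that bound was too low, as another labelling gave 0.406 and 3 of 70 (one-sided permutation p = 0.0429) or 3 of the 16 within pairs (p = 0.188) reached it, so the called miRNAs alone stay open too. The same column layout on both slides cannot be told apart from a shared effect, since 0 columns held both treatments. A response of the same miRNAs in both tissues may be present only as a hypothesis. Regrouped by the other tissue's letter codes, the correlation was -0.394 with plasma and -0.542 with kidney. That regrouping turns the treatment of 6 of 8 letters, so a change of sign largely follows from the 0.446 and decides nothing here.

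Chance could not be excluded for the kidney list count of 1, reached by 17 of 35 splits (highest other 3), or the interaction count of 1, reached by 11 of 100 drawn splits (highest other 4). For the tissue comparison of control pools, 1 of 35 splits, the real one, had 138 passing against 0 in any other. Every other split mixes the tissues within each group, and the detection filter was applied anew, though the 66 miRNAs detected on all control arrays stayed testable. With arrays taken as independent, although the tissues share rats, this argues against chance, but 1 of 35 is the smallest share possible. In plasma the real split had 0 passing miRNAs and 0 lists, which all 35 splits reach whatever the data, so the splits test nothing there (highest other 1 and 4). Among the 8 plasma splits that part all 4 pairs, the other splits gave at most 0 miRNAs and 3 lists, and the remaining splits at most 1 and 4.

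Of 238 groups of 4 arrays checked, 13 (5.5%) had 1 array far from the other 3, where chance gives about 1 in 20. In plasma these were the detected miRNAs of control pool 4 (84), and the log2 signals of miR-30d in control pool 1 (7.50), miR-409-3p in control pool 4 (7.29), miR-327 in CI-AKI pool 1 (9.42) and miR-466b in CI-AKI pool 3 (5.70). In kidney controls they were miR-27b in pool 4 (9.49), miR-23b in pool 3 (11.24) and miR-143 in pool 1 (9.80). The kidney CI-AKI pool 3 had 5 of the 13: its total signal (59740) and the log2 signals of miR-188 (4.32), miR-409-3p (4.96), miR-17-5p (5.71) and miR-126 (10.15). The effect on miR-327 differed between tissues by test, with an interaction of -2.63 (limma adjusted p = 0.000302), which was -1.95 at 2 times the floor.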

How the results depend on the processing

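Normexp, scaling to the labelling spike-in, leaving out both pool 4 plasma arrays and pairing the tissues by pool number were chosen only after the data were seen; the other alternatives given here were not. For the 109 named log2 differences, 2582 of 2809 alternative values kept their direction and their side of the threshold, 23 lost a call, 6 gained one and 198, of 56 differences, turned sign; of those 198, 0 were past the threshold in the alternative, and the smallest adjusted p among them was 0.119. Where not stated otherwise, the cause was not tested.

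The count of kidney miRNAs past the threshold was 4 with the percentile over all miRNAs, where miR-31 was added, 3 with median scaling, where miR-31 took the place of miR-494, 3 with the total signal per miRNA, in the authors' log2 table, scaled to the spike-in and without CI-AKI pool 3, where miR-188 did, 1 with quantile normalization, without scaling and with all 4 groups in 1 fit, and 0 with normexp and with detection required on every array, where miR-327 could not be tested because it was undetected in control pools. The count of plasma miRNAs was 1 without the pool 4 arrays and with the pool number as a block. Of the plasma lists, 1 passed with quantile normalization, in the authors' log2 table and with detection on every array (each time the followed-up miRNAs), and 1 with normexp (erythroid). Of the kidney lists, 0 passed with quantile normalization, without scaling, in the authors' log2 table, scaled to the spike-in, with an estimated correlation and in fry, and 2 passed with normexp (hypoxia and let-7) and with detection on at least 1 array (let-7 and Dlk1-Dio3). The interaction count was 0 without scaling, with normexp and with detection on every array, 2 with the total signal per miRNA (miR-188 and miR-327), 2 without the pool 4 arrays (miR-327 and miR-347) and 1 with the tissues paired (miR-327). Between tissues 57 passed without scaling, 73 with normexp and 56 with detection on every array, where fewer miRNAs were tested. The number was higher without plasma control pool 4 (176) and without both pool 4 plasma arrays (184). Without 1 pool at a time, plasma lists ranged from 0 to 1, kidney lists from 0 to 1 and the interaction from 1 to 4; the difference in detected plasma miRNAs ranged from -35.9 to 15.3, in plasma signal from -1.28 to 0.66 and in kidney signal from -0.14 to 0.20.

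With the pool number as a replicate block, 0 plasma miRNAs, 3 kidney miRNAs, 1 interaction and 135 tissue differences passed, and the permutation p was 0.625 and 0.875 for detected miRNAs and signal in plasma and 0.125 and 0.875 in kidney. In kidney, pools with the same number had correlations of 0.204, 0.588, -0.1 and 0.147, against -0.416 to 0.324 for different numbers. Whether the numbers pair the kidney pools thus stays open. With the block 0 kidney lists passed (let-7 camera adjusted p = 0.062, within a range of 9.41e-05 to 0.97). Of the 135 tissue differences with the block, 133 were among the 138 without it. The block changed no call among the plasma, kidney and interaction miRNAs when all pools were kept. The pool 4 plasma arrays were dim, with labelling spike-in signals of 51.8 and 164.1 against 928 to 3155 on the other plasma arrays. How far they limit the plasma result was not tested. Normexp on the mean spot signal was not run.

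With the percentile over all miRNAs, the turned values were plasma miR-466b -0.001, let-7i -0.061, miR-93 -0.062, miR-142-5p -0.042, miR-27a -0.056, miR-29c -0.075, miR-29a -0.097, miR-142-3p -0.099 and kidney miR-26b 0.005, miR-322 0.007, miR-16 0.018, miR-126 0.024, miR-92a 0.026, miR-200a 0.028, miR-21 0.029. With quantile normalization, the turned values were plasma miR-20a 0.032, miR-30c 0.014, miR-29a -0.041, miR-21 0.12 and kidney miR-7a* -0.027, miR-29a -0.019, miR-26b 0, miR-222 -0.069, miR-30e -0.055, miR-223 -0.014, miR-21 0. Without scaling, the turned values were plasma miR-466b -0.087, let-7i -0.056, miR-93 -0.057, miR-142-5p -0.037, miR-27a -0.051, miR-29c -0.07, miR-29a -0.092, miR-142-3p -0.094 and kidney miR-195 -0.014, miR-222 -0.01, miR-30e -0.015, miR-17-5p -0.016, miR-29c -0.031, miR-223 -0.029, miR-194 -0.031. With median scaling, the turned values were plasma miR-30b-5p 0.001, miR-92a 0.037, miR-17-5p 0.007, miR-16 0.042, miR-20a 0.025, miR-221 0.071, miR-30c 0.10, miR-451 0.13, miR-21 0.21 and kidney miR-29c -0.004, miR-223 -0.002, miR-194 -0.004. With normexp, the turned values were plasma miR-335 0.38, miR-195 0.31, miR-192 0.057, miR-98 0.78, miR-126* 0.52, miR-29b 0.072, miR-107 0.36, miR-30b-5p 0.31, miR-17-5p 0.41, miR-221 0.64, miR-30c 0.21, miR-300-5p 0.72, miR-29a -0.057. With the total signal per miRNA, the turned values were plasma miR-221 0.25. With the brightest probe, the turned values were plasma miR-21 0.014 and kidney miR-30d -0.005, miR-195 -0.013, miR-30e -0.024, miR-17-5p -0.05, miR-29c -0.028, miR-223 -0.028, miR-194 -0.037. With the authors' log2 table, the turned values were plasma miR-30b-5p 0.011, miR-30c 0.038, miR-29a -0.039, miR-21 0.041 and kidney miR-9* -0.04, miR-222 -0.065, miR-30e -0.06, miR-16 0.016, miR-223 -0.024, miR-194 -0.024, miR-126 0.031. Scaled to the labelling spike-in, the turned values were plasma miR-30e -0.061, miR-30a -0.038, miR-25 -0.20, miR-466b -0.23, let-7i -0.29, miR-93 -0.30, miR-142-5p -0.28, miR-27a -0.29, miR-29c -0.31, miR-409-3p -0.19, miR-29a -0.33, miR-142-3p -0.33 and kidney miR-29c -0.007, miR-223 -0.006, miR-194 -0.008. Without both pool 4 plasma arrays, with or without the pool number as a block, the turned values were plasma miR-122 0.26, miR-24 0.035, miR-143 0.07, miR-30b-5p 0.032, miR-221 0.07, miR-30c 0.13, miR-300-5p 0.83, miR-21 0.10. Over the pools left out in turn, the ranges that crossed 0 were in plasma miR-93 -0.019 to 0.26, miR-142-5p -0.071 to 0.37, miR-27a -0.084 to 0.33, miR-29c -0.075 to 0.34, miR-409-3p -0.63 to 1.49, miR-29a -0.093 to 0.22, miR-142-3p -0.20 to 0.28, miR-451 -0.38 to 0.22, miR-21 -0.17 to 0.17, miR-20a -0.43 to 0.085, miR-221 -0.31 to 0.052, miR-300-5p -0.68 to 0.42, miR-223 -0.55 to 0.12, miR-92a -0.29 to 0.017, miR-17-5p -0.42 to 0.074, miR-466b -0.13 to 0.48, miR-122 -1.05 to 0.005, miR-143 -0.70 to 0.003 and in kidney miR-204 -0.024 to 0.091, miR-143 -0.13 to 0.063, miR-16 -0.037 to 0.015, miR-29c -0.02 to 0.058, miR-126 -0.053 to 0.032, miR-21 -0.093 to 0.092, miR-222 -0.036 to 0.076, miR-223 -0.077 to 0.057, miR-200a -0.04 to 0.023, miR-145 -0.021 to 0.23, miR-194 -0.076 to 0.065, miR-92a -0.038 to 0.032, miR-199a-5p -0.02 to 0.13, miR-195 -0.017 to 0.081, miR-30e -0.052 to 0.078, miR-17-5p -0.041 to 0.079, miR-29b -0.11 to 0.005, miR-322 -0.063 to 0.003.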

Other observations

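The tests without the pool 4 plasma arrays, and the miRNAs named for them, were chosen only after the data were seen.

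With the 3 stronger pools per group, the plasma miRNAs with the smallest p were mostly higher after contrast medium, and none passed in limma without the block. The log2 differences were 1.56 (SE 0.32) for miR-347, 1.40 (SE 0.34) for miR-212, 1.41 (SE 0.36) for miR-327, 1.17 (SE 0.32) for miR-874, 1.08 (SE 0.31) for miR-188 and 1.28 (SE 0.37) for miR-133a, a muscle miRNA. That of miR-183 was -1.26 (SE 0.36). The signal of miR-347 was 15.6 in control and 47.1 in CI-AKI pools, that of miR-212 17.1 and 45.1, and that of miR-327 368 and 1029. The smallest adjusted p was 0.0616, for miR-347, followed by 0.108 for miR-212 and miR-327.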
